A study of Homo sapiens with 15 samples.

How the data were processed

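Polyadenylated RNA of HK-2, an immortalised human renal proximal tubule cell line, was sequenced in 15 libraries, in 5 groups of 3. Per the labels the cells were wild type and grew in DMEM/F12 with serum. One group was mock-treated with PBS and is labelled 0 h. A pair of groups received TGF-beta (TGFb) at 2 ug/ml with the DMSO vehicle for 1 h or 12 h, and another pair received the same TGFb with FT895, a selective inhibitor of histone deacetylase HDAC11, for 1 h or 12 h. The dose of FT895 is not given in the sources used here. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries.

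Per the submitters' processing notes, RNA was extracted with Trizol and treated with DNase I, Illumina reads were aligned to GRCh38 with HISAT2, and transcripts were quantified with StringTie. Versions, the annotation release and the strandedness of the libraries are not given in the sources used here. The deposited values are FPKM (fragments scaled by transcript length and by the mapped total), 1 column per library. The table holds 24880 loci, of which 19974 carry an Ensembl gene identifier and 4906 are unannotated loci assembled by the authors' pipeline. Symbols were taken from GENCODE v29 by Ensembl identifier, which matched 19883 genes, because 27 symbols in the table are written as dates. Coordinates are those of GENCODE v29 on GRCh38. None of the per-library columns was left unused. Reads of close paralogs cannot be checked from FPKM, and neither can antisense reads where no strand is stated.

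Read depth is unknown, because FPKM does not carry it. Whether low values are multiples of whole reads was tested on loci with FPKM above 0 and under 0.1 in both libraries of a replicate pair. In the 15 pairs there were 693 to 807 such loci, and the fullest bin of width 0.02 held 1.59 to 2.76% of their log2 ratios, so no read unit could be read from the values. For that reason no counting interval and no detection floor are given, and genes without signal are described as listed at 0.

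Values were analysed as log2(FPKM + 1), a scale that understates fold changes of genes near or under 1 FPKM. Genes with FPKM of at least 1 in at least 3 of the 15 libraries were tested, which left 12467, including 931 unannotated loci (7.47%). One linear model with a mean per group was fitted to all 15 libraries in limma 3.58.1 under R 4.3.3 (lmFit, eBayes with a mean-variance trend, 10 residual degrees of freedom, median prior degrees of freedom 4.34), so that the groups share an estimate of the spread. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison; tests were two-sided. The 6 comparisons were TGFb against mock at 1 h and at 12 h, FT895 with TGFb against vehicle with TGFb at 1 h and at 12 h, TGFb at 12 h against 1 h, and the FT895 effect at 12 h minus that at 1 h (an interaction). Mock, which per the labels received PBS, differs from the treated groups in time in culture and in the DMSO vehicle as well as in TGFb.

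A total of 31 gene lists were fixed: TGF-beta/SMAD direct targets, TGF-beta pathway components, collagens and extracellular matrix, matrix crosslinking and remodelling enzymes, mesenchymal and contractile genes, epithelial junction and keratin genes, proximal tubule genes, tubular injury genes, histone deacetylases and sirtuins, Kruppel-like factors, fatty acid oxidation, glycolysis, immediate early genes, inflammatory cytokine and NF-kB genes, interferon-stimulated genes, mitosis, DNA replication, p53 targets and senescence, ATF4 and unfolded protein response, heat shock, NRF2 targets, hypoxia, metallothioneins, cholesterol synthesis and SREBP2, YAP/TAZ targets, mitochondrially encoded genes, cytosolic ribosomal proteins, and markers of fibroblasts and pericytes, endothelium, leukocytes, and distal nephron and podocytes. Lists with at least 5 tested members (28 of them) were tested with limma's camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists within a comparison. Camera was repeated with a correlation estimated per list, and limma's fry was run as a test of whether a list's own genes move, on balance, one way. Member counts are given over all genes tested and adjusted over the list alone.

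The genes, lists, comparisons, thresholds and alternatives were chosen before the data were examined. Named genes were taken from a rule with 4 parts, and a few genes that it gives are not named. The first part is HDAC11 and 14 landmark genes of TGF-beta signalling, matrix, epithelial state and metabolism in each main comparison, called or not (12 of the 15 passed the filter). The second is the 8 largest rises and 8 largest falls per main comparison among called genes with a symbol, groups that do not overlap, and a mean of at least 5 FPKM in the higher group. The third is up to 4 called members of largest change per list, or up to 2 of smallest p where none was called. The fourth is the 5 most positive and 5 most negative interaction genes with a mean of at least 5 FPKM in any of the 4 groups. A gene outside the rule is named only with the remark that it was chosen after its values were seen.

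Overlaps of called genes were set beside the number expected from independent draws. For comparisons that share libraries, the covariance of fold changes was set beside 100 simulations of unchanged groups, since shared libraries alone give correlated changes. Alternatives were a pseudocount of 0.1, no filter on low values, a filter at 5 FPKM, median-of-ratios scaling, quantile normalization, no mean-variance trend, library weights from limma's arrayWeights, a replicate block, a fit with only the groups compared, an absolute log2 change of at least 1, and the omission of each of the 15 libraries in turn. Other splits of the libraries into groups of equal size were fitted with the same model. The model was tested on simulated data in which 200 genes per run, over 5 runs, were changed by a known amount. Among genes with a mean of at least 5 FPKM, changes of 0.25, 0.5 and 1 on the log2 scale were recovered for 13.7, 78.6 and 97.9% of genes in the FT895 comparison at 12 h and for 12.9, 79.5 and 99.2% at 1 h, and false calls made up 3.16 to 5.54% of calls over the 4 main comparisons. All simulated libraries shared the same spread for a gene. The recovery and false-call rates therefore do not cover a library of wider spread, such as TGFb 1 h replicate 1 in the 1 h comparisons. In 200 random lists without a planted shift, camera gave p under 0.05 for 10. The simulated genes were independent, so this says nothing about false calls for lists whose genes are correlated. Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9 prepared the annotation and drew the figures.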

Results

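The data describe how HK-2 cells, which keep part of the character of the proximal tubule epithelium, respond to TGFb. They also describe how expression under TGFb differs when the HDAC11 inhibitor FT895 is added. No group received FT895 without TGFb, so a change of the TGFb response cannot be told apart from an effect of FT895 by itself. TGFb is the main signal that drives tubule cells toward matrix production in renal fibrosis, and HDAC11 removes acyl groups from proteins. Each of the 5 groups (mock; TGFb at 1 h and at 12 h; TGFb with FT895 at 1 h and at 12 h) held 3 libraries. Read depth is unknown. Summed FPKM per library ran from 386532 to 434520, and 11712 to 12023 loci reached 1 FPKM. The 50 highest loci held 23.3 to 27.4% of the sum.

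Time under TGFb was the widest separation between libraries. The first principal component carried 55.3% of the variance and placed the 6 libraries of 12 h apart from the 9 of mock and 1 h, and the second carried 11.7%. Library TGFb 1 h replicate 1 stood apart from its group. Its PC2 score was -25 against -3.4 and -6.4 for replicates 2 and 3. Its summed FPKM of 434520 was the highest (the other 14 reached at most 406560), and its residual SD was 0.211 on the log2 scale against 0.107 to 0.156 elsewhere. Spearman correlations between libraries of a group were at least 0.98 across genes, which are not independent replicates.

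**Figure D1:**
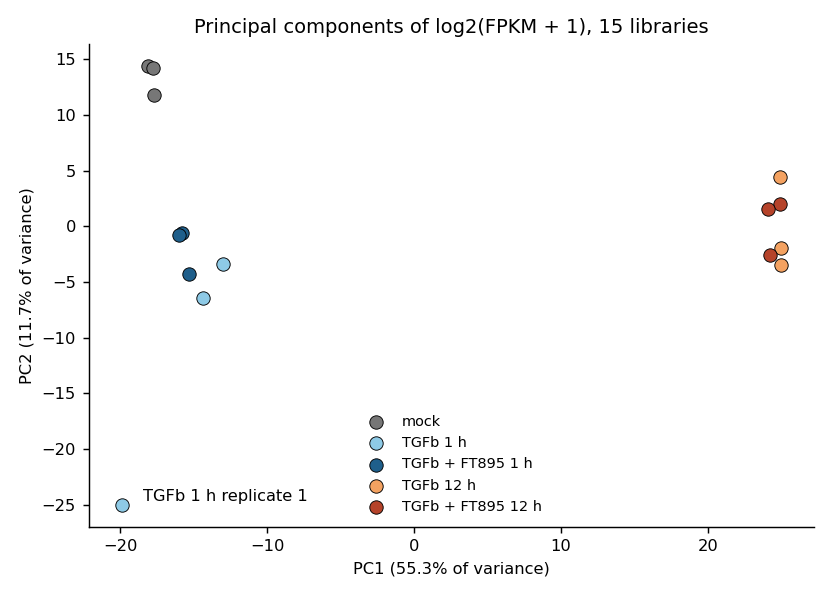
Principal components of log2(FPKM + 1) for the 15 libraries, with 1 point per library coloured by group; the axes are scores on PC1 (55.3% of variance) and PC2 (11.7%). The 12 h libraries lie apart on PC1, and TGFb 1 h replicate 1 lies at -25 on PC2.

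Cell identity markers set the background for the tubular lists. HDAC11 itself (chromosome 3, 13479724 to 13506424, plus strand, a protein-coding gene as are all others with coordinates given here) was expressed at a low level: 2.79 ± 0.354 FPKM in mock (mean ± SD, n = 3 here and in all groups), 3.25 ± 0.198 and 2.65 ± 0.356 with TGFb at 1 h and 12 h, and 3.07 ± 0.138 and 2.74 ± 0.193 with FT895 added. It was not called in any of the 6 comparisons, with the smallest adjusted p at 0.0592 for TGFb at 12 h against 1 h (log2 change -0.22). CDH1, the cadherin of epithelial junctions, and KLF15, a tubular transcription factor that restrains fibrosis, were listed at 0 in all 15 libraries, and ACTA2, the smooth muscle actin of myofibroblasts, reached at most 0.558 FPKM, so none of these landmarks was tested. CDH2, the cadherin that proximal tubule cells share with mesenchyme, was at 94 ± 0.441 FPKM in mock. Markers of other cell types were sparse: 2 of 13 endothelial, 3 of 14 leukocyte and 3 of 16 distal nephron and podocyte genes passed the filter, so those lists were not tested, and the fibroblast and pericyte list had 5 measured members. With no filter on low values that list had 12. The proximal tubule list had 12 members with the filter and 27 without it, so many genes of the cells' own type were low as well.

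After 1 h, TGFb had raised its direct SMAD targets as a group. The largest rises were those of the transcription factor HES1, the cytokine IL11 and the repressor SNAI1. Structural matrix and mesenchymal genes were not called as groups. The comparison of TGFb at 1 h with mock asks which genes respond first. Mock is labelled 0 h, so time in culture differs as well, and so does the DMSO vehicle.

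Of 12467 genes, 1119 were called at 1 h: 461 rose and 658 fell, and 61 (52 up, 9 down) changed by at least 1 on the log2 scale. The share of calls that rose was 41.2%, and 53.2% with median-of-ratios scaling, which by its construction draws the share toward 50%. The number and balance of calls also depend on mock libraries: 441 genes were called without mock replicate 1 (55.3% up), 549 without mock replicate 2 (49% up) and 416 without mock replicate 3 (55% up). Without TGFb 1 h replicate 1 it was 1059.

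The transcription factor HES1, a repressor best known downstream of Notch (chromosome 3, 194136145 to 194138732, plus strand), showed the largest rise, from 6.44 ± 0.521 to 83.3 ± 3.8 FPKM (log2 change 3.5, adjusted p 9e-13). IL11, a cytokine of the interleukin-6 family that acts in fibrosis, went from 7.51 ± 0.258 to 66.1 ± 3.43 FPKM (2.98). SNAI1, which encodes the Snail repressor of epithelial genes (chromosome 20, 49982999 to 49988886, plus strand), rose by 2.79 to 42.3 ± 3.95 FPKM (adjusted p 1.36e-11). The AP-1 subunit JUNB rose by 2.65 and the stress sensor GADD45B, itself a SMAD target, by 2.4. ID1, an inhibitor of helix-loop-helix factors and a classical target of SMAD1/5, rose by 2.41, from 31 ± 4.01 to 169 ± 25.2 FPKM. DLX2, a homeobox factor, rose by 2.3 from a low level of 0.666 ± 0.058 to 7.23 ± 0.851 FPKM. SMAD7, the inhibitory SMAD that closes the feedback loop on the receptor (chromosome 18, 48919853 to 48952052, minus strand), rose by 2.15, from 7.22 ± 0.194 to 35.6 ± 0.784 FPKM (adjusted p 1.18e-12). The co-repressor SKIL, another feedback gene, rose by 1.01 (adjusted p 0.00066), and the matricellular gene CCN2 rose by 0.93, from 96 ± 0.323 to 184 ± 6.7 FPKM (adjusted p 5.05e-08).

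The deepest fall was that of CITED2, a CBP/p300-binding coregulator that competes with HIF and modulates SMAD transcription, from 126 ± 3.31 to 36.5 ± 2.11 FPKM (-1.77). The chemokine CXCL2 fell by 1.75 and the growth-factor-responsive PHLDA1 by 1.57. The secreted protease ADAMTS1 fell by 1.06, the doublesex-related factor DMRTA1 by 1.04, the zinc-finger factor KLF6 by 0.99 and the arrestin-like ARRDC3 by 0.99. KRTAP2-3, a keratin-associated gene with close paralogs whose reads cannot be told apart in FPKM, fell by 1.01. The remaining landmarks were not called: COL1A1 (log2 change 0.19, adjusted p 0.194), COL4A1 (-0.21, 0.139), VIM (-0.09, 0.385), CDH2 (-0.11, 0.184), CPT1A (-0.2, 0.136) and FN1 (-0.45, 0.11; -0.147 without TGFb 1 h replicate 1).

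The TGF-beta/SMAD direct targets led the lists, with 21 of 33 members called up and 0 down (22 up and 1 down adjusted over the list alone), a median log2 change of 0.541 and a camera adjusted p of 1.34e-29 (0.0216 with an estimated correlation). Immediate early genes rose with a median of 0.269 (14 up and 4 down of 27; 14 and 6 adjusted over the list alone; adjusted p 3.89e-09, and 0.0424 with an estimated correlation). Among them IER3, an apoptosis modulator, rose by 1.97 and ZFP36, which destabilises cytokine mRNAs, by 1.93. Several members ran against the list, chosen here after their values were seen: MYC, which TGFb represses in epithelia, fell by 0.76, the ERK phosphatase DUSP6 by 0.61 and the kinase SGK1 by 0.50. NRF2 targets, the antioxidant programme, rose with a median of 0.093 (4 up, 0 down of 24; 7 up adjusted over the list alone; adjusted p 0.000639, and 0.0406 with an estimated correlation; median 0.055 without mock replicate 3). The heme-degrading enzyme HMOX1, which the SMAD list also holds, led it with a rise of 0.73.

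A further 4 lists were called upward, and each lost its call once the correlation was estimated. Hypoxia genes had 5 of 25 up and 0 down (5 adjusted over the list alone), a median of 0.026 and an adjusted p of 0.00135 (adjusted p = 0.154 with an estimated correlation; 0.104 with quantile normalization). Among its risers were ANGPTL4, an inhibitor of lipoprotein lipase (1.51), the angiogenic factor VEGFA (1.06) and PFKFB3 (0.92), which sets fructose-2,6-bisphosphate and so glycolytic flux. The other 20 members were not called. The median ranged from 0.01 without TGFb 1 h replicate 2 and 0.011 without mock replicate 3 to 0.048 without TGFb 1 h replicate 1 and 0.059 without mock replicate 2. Glycolysis genes had 2 of 20 up and 0 down (2 adjusted over the list alone; median 0.087, adjusted p 0.0272, and 0.515 with an estimated correlation). The call was lost without mock replicate 3 (0.0597), TGFb 1 h replicate 2 (0.0732, median 0.046) or TGFb 1 h replicate 3 (0.0637, median 0.054). The median turned to -0.045 with quantile normalization. Inflammatory cytokine and NF-kB genes split into 9 up and 7 down of 26 (11 and 7 adjusted over the list alone; median 0.081, adjusted p 0.0272, and 0.444 with an estimated correlation). Here IL11, the myeloid growth factor CSF2 (1.45) and IRF1 (0.89) rose while CXCL2 fell. The call was lost without TGFb 1 h replicate 2 (0.121), and the median was 0.123 without mock replicate 1, 0.132 without TGFb 1 h replicate 1 and 0.142 without TGFb 1 h replicate 3. Cytosolic ribosomal protein genes had 4 of 75 up and 0 down (0 adjusted over the list alone), with a median of 0.262 and an adjusted p of 3.38e-14 (0.456 with an estimated correlation). Without TGFb 1 h replicate 1 the median was 0.074 (adjusted p 0.000216).

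Among lists not called at 1 h, several held genes that moved strongly in opposite directions. Kruppel-like factors (2 up and 2 down of 10, over all genes and adjusted over the list alone; adjusted p 0.843) combined a rise of 1.95 in KLF10, the TGFb-inducible early gene, with falls of KLF6 and of KLF5 (-0.87), a driver of epithelial growth. p53 targets (4 up, 3 down of 30; 5 and 3 adjusted over the list alone; 0.33) combined rises of the kinase PLK3 (1.1) and of the cell-cycle inhibitor CDKN1A (0.97) with falls of PLK2 (-0.79) and GADD45A (-0.44). The epithelial junction list (2 up, 3 down of 21; 4 and 4 adjusted over the list alone; 0.167) held a rise of the tight-junction gene CLDN4 (1.42) and of KRT8 (0.42) and a fall of CLDN1 (-0.43). YAP/TAZ targets (3 up, 5 down of 26; 4 and 6 adjusted over the list alone; 0.494) had a median of -0.113 and a mean of 0.004, with GADD45B and CCN2 up and the clotting initiator F3 down by 0.64. The mesenchymal and contractile list (5 up, 0 down of 23, in both counts; 0.0916) had a median of -0.021 against a mean of 0.17, carried by SNAI1, the lipid kinase SPHK1 (1.08) and the actin-binding TAGLN (0.48). It was called without mock replicate 2 (0.0408) or TGFb 1 h replicate 1 (0.0292). ATF4 and unfolded protein response genes (3 up, 3 down of 37 in both counts; 0.0539) included rises of ATF3 (0.81), the amino-acid transporter SLC7A5 (0.53) and the mTORC1 inhibitor DDIT4 (0.48). This list was called without mock replicate 1 (0.0471), TGFb 1 h replicate 3 (0.0467) or TGFb + FT895 12 h replicate 1 (0.0487).

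Lists of tissue state stayed below the threshold at 1 h. Collagens and extracellular matrix had 2 up and 5 down of 31 (2 and 8 adjusted over the list alone; median -0.203, adjusted p 0.0734, but 0.00884 and called down with quantile normalization), with the activin antagonist FSTL3 up by 0.61. They were called down without TGFb 1 h replicate 2 (-0.303, adjusted p 0.000356) or replicate 3 (0.0381). Both omissions give more weight to TGFb 1 h replicate 1, the library that stands apart from its group. Matrix crosslinking and remodelling enzymes had 3 up and 1 down of 27 in both counts (0.108), with the urokinase receptor PLAUR up by 0.37, and were called up without TGFb 1 h replicate 1 (0.00814). TGF-beta pathway components had 0 up and 4 down of 22 (1 and 4 adjusted over the list alone; 0.456), among them the integrin subunit ITGB6, which activates latent TGFb (-0.52), and TGFB2 (-0.3). Proximal tubule genes had 0 up and 2 down of 12 in both counts (0.0916): the peptidase MME (-0.55) and the cadherin CDH6 (-0.38). Cholesterol synthesis genes had 0 up and 4 down of 29 in both counts (0.224, but 0.0226 and called down with quantile normalization), with HMGCS1, an early enzyme of the pathway, down by 0.45. Mitosis genes had 0 up and 3 down of 34 (0 and 7 adjusted over the list alone; 0.285), with the kinetochore gene CENPF at -0.5; the list was called down with quantile normalization (0.00884), with library weights (0.0452) and without TGFb 1 h replicate 1 (0.0144).

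The other lists tested at 1 h had adjusted p of 0.101 (metallothioneins, 0 called of 5; 0.0198 and 0.0467 without TGFb 1 h replicates 2 and 3), 0.108 (heat shock, 3 up of 23, with the co-chaperones DNAJB1 at 0.34 and BAG3 at 0.3), 0.167 (interferon-stimulated, 2 down of 27 and 0 adjusted over the list alone), 0.301 (fatty acid oxidation, 2 up and 2 down of 28), 0.312 (histone deacetylases and sirtuins, 1 down of 17), 0.312 (DNA replication, 1 up and 1 down of 38; 1 and 0 adjusted over the list alone), 0.895 (tubular injury, 3 down of 20; 1 and 3 adjusted over the list alone; median -0.016, while camera's direction was up), 0.895 (mitochondrially encoded, 0 called of 13) and 0.895 (fibroblast and pericyte markers, 0 called of 5).

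**Figure D2:**
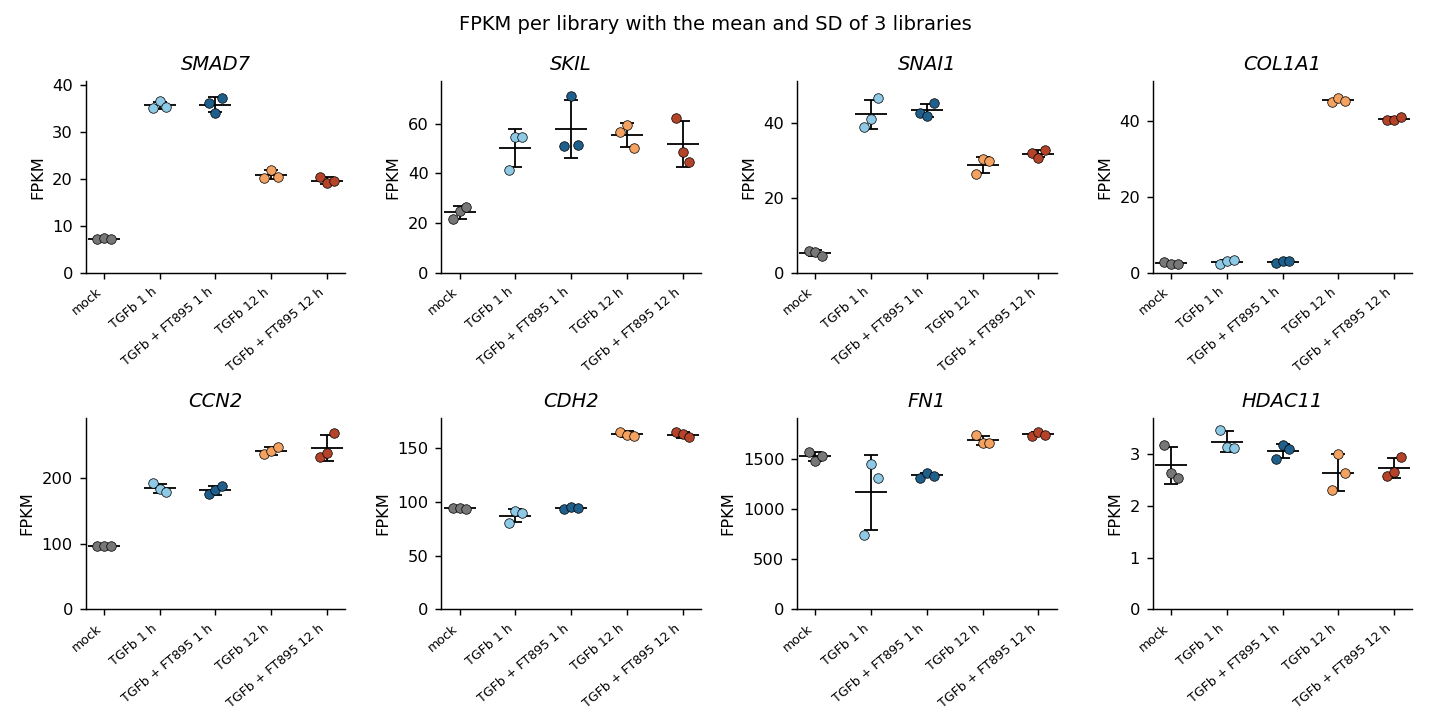
FPKM of 8 landmark genes in each of the 15 libraries by group (points), with mean and SD of 3 libraries as bars; each vertical axis starts at 0. SMAD7 and SNAI1 were highest at 1 h, while COL1A1, CCN2 and CDH2 were highest at 12 h, with or without FT895.

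After 12 h of TGFb, collagen I (COL1A1) and, as a group, the mesenchymal and contractile genes were higher than in mock. Amphiregulin and epiregulin, ligands of the EGF receptor, fell steeply. Genes of DNA replication fell as a group. The tubule transcription factor PAX8 and the bicarbonate cotransporter SLC4A4 fell. The comparison with mock asks which state the cells reach. Mock is labelled 0 h and received PBS, and no vehicle group matches 12 h. Effects of TGFb therefore cannot be told apart here from those of 12 h in culture or of the DMSO vehicle.

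At 12 h 4814 genes were called (1765 up, 3049 down), 389 of them (233 up, 156 down) by at least 1 on the log2 scale. The share that rose was 36.7%, against 52.9% with median-of-ratios scaling and 46.9% with quantile normalization. Of the 1119 genes called at 1 h, 666 were also called at 12 h. Among these, 255 were up at both times (65.3 expected from independent draws) and 333 down at both (161 expected), while 38 went from up to down (113 expected) and 40 from down to up (93.2 expected). The shared mock libraries give some concordance by themselves: the covariance of the fold changes was 0.037 against 0.00598 in simulated unchanged groups. The Pearson r was 0.381 against 0.359 there. The expected counts leave out the shared mock, and the simulation draws genes independently. How much of the concordance lies beyond the shared mock is therefore not settled.

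COL1A1, the alpha-1 chain of collagen I (chromosome 17, 50183289 to 50201632, minus strand), rose from 2.44 ± 0.229 to 45.4 ± 0.452 FPKM (log2 change 3.75, adjusted p 3.91e-13). CGB5 and CGB8, genes for beta subunits of chorionic gonadotropin, a placental hormone, rose more than COL1A1. CGB5 (chromosome 19, 49043884 to 49045311, plus strand) went from 0.316 ± 0.16 to 26.3 ± 1.35 FPKM (4.38). CGB8 went from 1.16 ± 0.334 to 36.7 ± 0.672 (4.14). A further copy, CGB3, rose less than COL1A1, from 0.265 ± 0.139 to 9.61 ± 0.734 (3.07). These genes are near-identical copies, so the split of reads between them is uncertain. IL11 rose further, to 93.3 ± 2.37 FPKM (3.47). ODAPH, a phosphoprotein gene of tooth enamel, rose by 3.42, the RNA-binding CSDC2 by 3.11 and the angiopoietin-like ANGPTL7 by 2.84, the last from 0.0294 ± 0.051 to 6.4 ± 0.942 FPKM. CCN2 reached 241 ± 5.78 FPKM (1.32), COL4A1, a basement membrane collagen, 416 ± 10.7 (0.78) and CDH2 (chromosome 18, 27950966 to 28177446, minus strand) 163 ± 2.38 (0.79). SNAI1 (2.25), SMAD7 (1.41) and SKIL (1.15) were still above mock. The intermediate filament gene VIM rose by 0.28 (adjusted p 0.00312), a call that was lost with quantile normalization. FN1, the fibronectin gene, was not called (0.14, adjusted p 0.529). The carnitine palmitoyltransferase gene CPT1A, the gate to mitochondrial fatty acid oxidation, fell by 0.49 (adjusted p 0.000303).

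The largest fall was that of CAVIN2, a caveolar coat gene, from 18.8 ± 0.733 to 0.682 ± 0.0224 FPKM (-3.56). AREG, which encodes amphiregulin (chromosome 4, 74445134 to 74455009, plus strand), fell from 46.1 ± 2.14 to 3.05 ± 0.681 FPKM (-3.55), and its neighbour EREG, epiregulin (chromosome 4, 74365143 to 74388751, plus strand), from 62.9 ± 0.662 to 9.05 ± 0.581 (-2.67). The integrin subunit ITGB8, which activates latent TGFb, fell by 2.81, to 1.22 ± 0.0958 FPKM. The tetraspanin-like TM4SF18 fell by 2.49, CITED2 by 2.17 and NABP1, a single-strand DNA-binding gene, by 2.12.

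Among lists, SMAD targets had 26 of 33 up and 1 down, in both counts (median 1.128, adjusted p 7.08e-22, and 0.0206 with an estimated correlation). LMCD1, a LIM-domain cofactor, rose by 2.54, while ID2 (chosen after its values were seen) fell by 0.61 although it had risen at 1 h. Mesenchymal and contractile genes had 14 up and 1 down of 23 (15 and 1 adjusted over the list alone; median 0.317, adjusted p 1.78e-09, and 0.00684 with an estimated correlation). They were led after SNAI1 by SPHK1 (1.74), calponin CNN1 (1.53) and TAGLN (1.17). The hyaluronan receptor CD44, chosen after its values were seen, fell (-0.41, adjusted p 0.0387). DNA replication genes had 0 up and 28 down of 38 (29 down adjusted over the list alone; median -0.409, adjusted p 1.62e-08, and 0.00684 with an estimated correlation). The G1/S cyclin CCNE2 (-1), the activator E2F2 (-0.96), the histone mRNA-binding SLBP (-0.85) and the helicase subunit MCM3 (-0.73) fell. These 3 lists, and no others at 12 h, stayed called with an estimated correlation.

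Matrix remodelling enzymes rose at the preset correlation (15 up and 5 down of 27; 16 and 6 adjusted over the list alone; median 0.525, adjusted p 1.52e-06, and 0.163 with an estimated correlation). The metalloprotease ADAM19 (1.59), the collagen crosslinker LOX (1.43) and the prolyl hydroxylase subunit P4HA3 (1.18) rose. Collagens and extracellular matrix had 16 up and 6 down of 31 in both counts (median 0.238, adjusted p 2.1e-05, and 0.47 with an estimated correlation). FSTL3 (1.56) and TGFBI (1.13) rose with COL1A1, whereas COL8A1 (-0.98) and the laminin chain LAMA3 (-0.75), both chosen after their values were seen, fell. ATF4 and unfolded protein response genes had 19 up and 3 down of 37 (20 and 3 adjusted over the list alone; median 0.225, adjusted p 1.52e-06, and 0.0549 with an estimated correlation). Among them rose the amino-acid exchangers SLC7A5 (1.4), SLC7A11 (0.71) and their partner SLC3A2 (0.7), and the ER-resident MANF (0.84). Mitosis genes had 19 up and 1 down of 34 (20 and 1 adjusted over the list alone; median 0.226, adjusted p 3.99e-06, and 0.169 with an estimated correlation). The kinases NEK2 (0.5) and PLK1 (0.42) and the motor KIF2C (0.4) rose, and the cytokinesis factor ECT2 fell by 0.43. Immediate early genes had 11 up and 5 down of 27 (11 and 7 adjusted over the list alone; median 0.052, adjusted p 0.00558, and 0.336 with an estimated correlation; the median was -0.005 without the filter on low values), with EGR2 (2.07), IER3 (1.95) and HES1 (1.72) up. TGF-beta pathway components had 12 up and 6 down of 22 in both counts (median 0.242, adjusted p 0.0103, and 0.47 with an estimated correlation). The ligand TGFB1 (1.24) and the receptor BMPR2 (0.92) rose and the signal transducer SMAD3 fell by 1.03. Proximal tubule genes had 1 up and 8 down of 12 in both counts (median -0.484, adjusted p 0.00919, and 0.163 with an estimated correlation; 0.295 without the filter on low values). The bicarbonate cotransporter SLC4A4 (-1.09), the nephric factor PAX8 (-1.06) and the brush-border peptidases MME (-0.68) and DPP4 (-0.58) fell, and CDH6 rose by 0.31.

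Hypoxia genes were not called at 12 h (7 up and 2 down of 25 in both counts; median -0.008 against a mean of 0.309; adjusted p 0.0727, but 0.0368 and called up with median-of-ratios scaling), although ANGPTL4 (2.65) and VEGFA (1.81) rose strongly. The list was called up without mock replicate 2 (0.0484) or TGFb 12 h replicate 3 (0.0471). Interferon-stimulated genes had 1 up and 9 down of 27 in both counts (0.231), with the antiviral genes IFIT2 and IFIT3 down by 1.01 and 0.87. p53 and senescence genes had 8 up and 7 down of 30 (9 and 7 adjusted over the list alone; median -0.057, mean 0.086; 0.351). The CDK inhibitor CDKN2B (1.76) and the growth-factor-binding IGFBP3 (1.65), both TGFb-responsive, rose, and GDF15 (-1.21) and the death receptor FAS (-0.86) fell. The epithelial list had 6 up and 6 down of 21 (6 and 8 adjusted over the list alone; median -0.154, camera's direction up; 0.998), with KRT7 (1.56) and CLDN4 (1.41) up and KRT19 (-1.49) and the polarity gene PARD6B (-1.31) down. Tubular injury genes had 8 up and 9 down of 20 in both counts (0.998), with the annexin ANXA1 (-1.29) and IL18 (-1) down and ITGB6 (0.91) up. NF-kB genes had 7 up and 10 down of 26 in both counts (0.998), with BIRC3 (-1.9) and CXCL2 (-1.74) down. Fatty acid oxidation had 5 up and 8 down of 28 (5 and 10 adjusted over the list alone; 0.998). The nuclear receptor PPARD (1.57) and the peroxisomal ACOX3 (1.51) rose and the coactivator PPARGC1A fell by 1.28.

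YAP/TAZ targets had 4 up and 12 down of 26 (4 and 13 adjusted over the list alone; 0.439), and NRF2 targets 4 up and 10 down of 24 (4 and 11 adjusted over the list alone; 0.6), with the heme transporter SLC48A1 down by 0.91 and HMOX1 up by 0.81. The fibroblast and pericyte list had 2 up and 2 down of 5 (0.462; median -0.218, mean 0.612): COL1A1 and NOTCH3 (0.46) rose while the proteoglycan LUM fell by 0.71. Glycolysis had 3 up and 4 down of 20 in both counts (0.998), with hexokinase HK2 down by 0.62 and PFKP up by 0.61. Cholesterol synthesis had 3 up and 9 down of 29 in both counts (0.998), with the sterol carrier STARD4 up by 0.82. Heat shock had 7 up and 4 down of 23 in both counts (0.201; median -0.016, mean 0.054), with HSPB8 (0.83) and HSPA1A (0.68) up. Kruppel-like factors had 2 up and 2 down of 10 (0.998; KLF7 0.86, KLF5 -1.11). Histone deacetylases and sirtuins had 3 up and 4 down of 17 in both counts (0.998), with HDAC1 up by 0.29. Metallothioneins had 1 up and 1 down of 5, mitochondrially encoded genes 0 called of 13, and cytosolic ribosomal proteins 0 up and 1 down of 75 (0 adjusted over the list alone), all at an adjusted p of 0.998. Medians of the deacetylase, Kruppel-like and ribosomal lists were below 0 while camera's direction was up. In the untested lists, the macrophage growth-factor receptor CSF1R rose from 0.151 ± 0.0395 to 2.64 ± 0.0198 FPKM (1.66) while the other leukocyte genes CD68 (-0.27, called) and CD74 (0.01, not called) did not rise. ESAM, an endothelial adhesion gene, rose by 0.49, the podocyte genes PODXL and SYNPO rose by 0.76 and 0.63, and the channel subunit SCNN1A fell by 0.79.

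**Figure D3:**
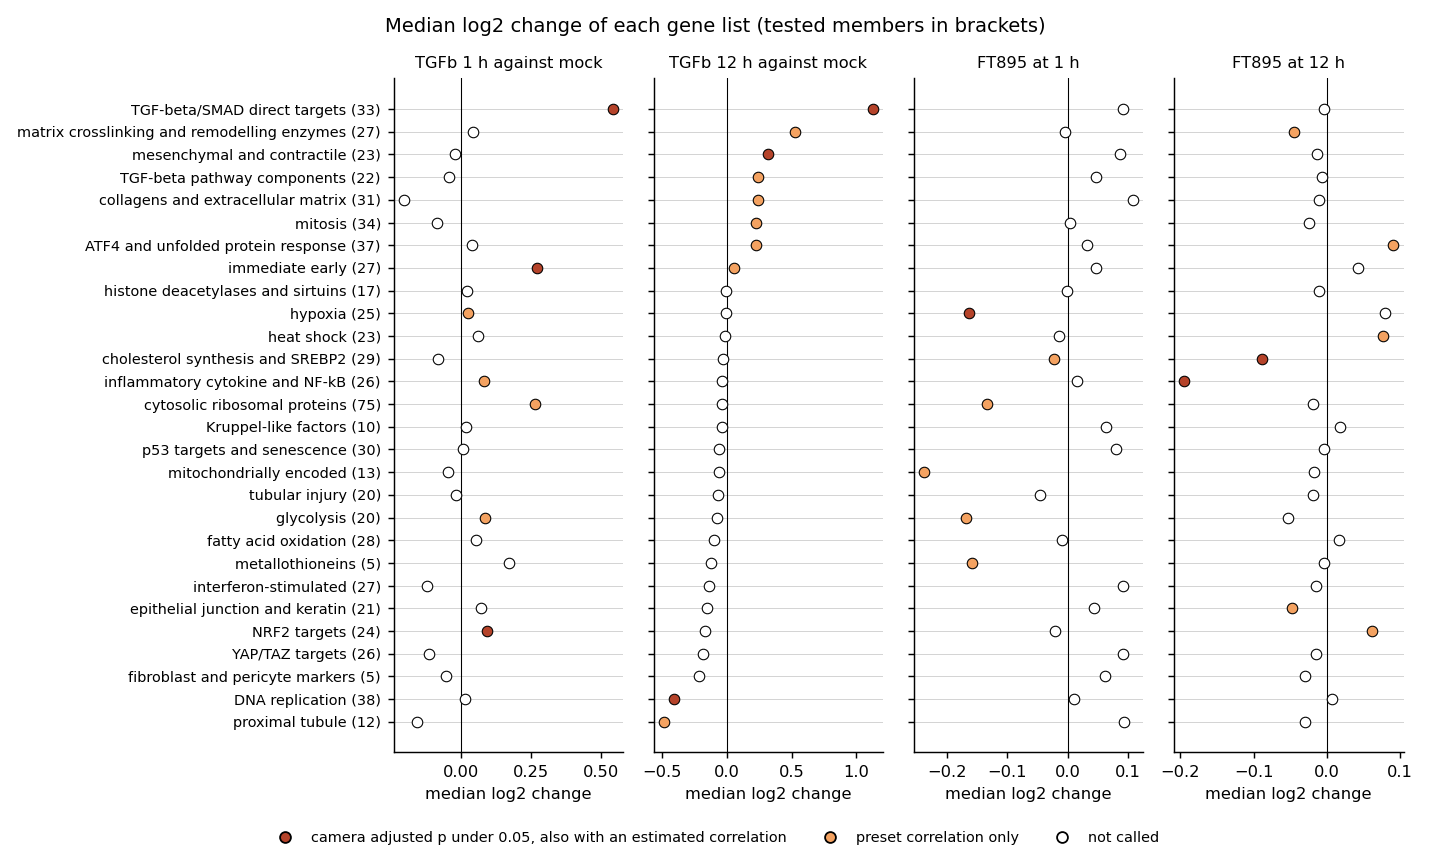
Median log2 change of the fixed gene lists in the comparisons, with filled marks for lists called by camera at its preset correlation and the darker fill for those also called with an estimated correlation. SMAD targets reached medians of 0.541 at 1 h and 1.128 at 12 h; the ribosomal list reached 0.262 at 1 h and -0.134 with FT895 at 1 h, and the latter was 0.035 without TGFb 1 h replicate 1.

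Between 1 h and 12 h under TGFb the early regulators ID1 and HES1 receded, and the collagen genes COL1A1 and COL4A1 rose. This comparison holds the ligand constant and asks how expression develops under it, although time in culture differs as well. It called 5113 genes, 2100 up and 3013 down (41.1% up, 51.3% with median-of-ratios scaling), and 300 by at least 1 on the log2 scale. ID1 dropped by 2.33, back to 32.6 ± 1.29 FPKM, and HES1 by 1.78, while SMAD7 and SNAI1 fell by 0.75 and 0.54. COL1A1 rose by 3.57, COL4A1 by 0.99, CDH2 by 0.9, CCN2 by 0.39 and VIM by 0.37, and CPT1A fell by 0.28. FN1 rose by 0.59 (adjusted p 0.0115), from 1170 ± 376 FPKM at 1 h, a value that depends on TGFb 1 h replicate 1. Against mock FN1 was not called at 12 h (0.14, adjusted p 0.529). SKIL was at 0.15 (adjusted p 0.449).

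DNA replication genes (0 up, 31 down of 38; 32 down adjusted over the list alone; median -0.393, adjusted p 2.24e-10, and 0.00516 with an estimated correlation) and mesenchymal genes (15 up, 2 down of 23 in both counts; median 0.373, adjusted p 4.99e-06, and 0.039 with an estimated correlation) moved in either test. The other called lists lost their calls with an estimated correlation: collagens (19 up, 2 down of 31; 20 and 3 adjusted over the list alone; 6.14e-08, then 0.411), mitosis (21 up, 1 down of 34; 23 and 1; 1.63e-07, then 0.166), matrix enzymes (15 up, 5 down of 27; 16 and 5; 1.53e-05, then 0.205), ATF4 genes (17 up, 4 down of 37; 18 and 4; 0.000902, then 0.205), TGF-beta pathway components (12 up, 5 down of 22; 12 and 6; 0.0126, then 0.617), SMAD targets (16 up, 10 down of 33; 17 and 10; 0.016, then 0.702), NRF2 targets (3 up, 15 down of 24 in both counts; 0.016, then 0.166) and cytosolic ribosomal proteins (0 up, 34 down of 75; 45 down; 1.93e-05, then 0.702). The ribosomal median was -0.314, and -0.122 without TGFb 1 h replicate 1. The other 18 lists were not called, the closest being proximal tubule genes (1 up, 7 down of 12 in both counts; 0.0938) and glycolysis (0.114; 0.0325 without TGFb 12 h replicate 2). Medians of the hypoxia, heat shock, p53 and fibroblast lists were below 0 with camera's direction up.

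FT895 added to TGFb for 1 h lowered 9 genes, among them PFKFB4 and EGLN1 of the hypoxia list and the mTORC1 inhibitor DDIT4. The hypoxia list moved down as a group. None of the TGFb landmarks was called. The question is whether adding FT895 changes expression after 1 h of TGFb. All 9 called genes fell, from a background of 1720 genes (13.8%) at an unadjusted p under 0.05, and 7 of the 9 were also called without TGFb 1 h replicate 1. Library weights, with which the TGFb 1 h group rests largely on replicate 3, instead called 1434 genes up and 540 down.

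PFKFB4, a bifunctional regulator of glycolysis induced by HIF (chromosome 3, 48517684 to 48562015, minus strand), fell from 18 ± 1.37 to 11 ± 0.0442 FPKM (log2 change -0.66, adjusted p 0.000156). DDIT4, also known as REDD1, which restrains mTORC1 under hypoxia and energy stress (chromosome 10, 72273920 to 72276036, plus strand), fell from 105 ± 5.51 to 66.9 ± 0.453 FPKM (-0.64, 0.000156). PPP1R3C, which targets protein phosphatase 1 to glycogen (chromosome 10, 91628442 to 91633054, minus strand), fell from 6.61 ± 0.625 to 3.42 ± 0.0849 FPKM (-0.78, 0.000162). KCTD11, a ubiquitin ligase adaptor of the Hedgehog pathway (chromosome 17, 7351889 to 7354944, plus strand), which TGFb alone had raised from 7.05 ± 0.278 to 25.4 ± 0.521 FPKM, fell to 17.9 ± 0.489 (-0.48, 0.000412). CIART, a circadian repressor below the level of the naming rule and named after its values were seen, fell from 3.89 ± 0.192 to 1.86 ± 0.046 FPKM (-0.77, 0.00657). EGLN1, the prolyl hydroxylase PHD2 that marks HIF for degradation and is itself a HIF target (chromosome 1, 231363751 to 231425044, minus strand), fell from 18.2 ± 0.487 to 14.4 ± 0.567 FPKM (-0.32, 0.02). The endosomal GTPase RAB20 (-0.56, 0.02), the growth factor PDGFB (-0.41, 0.0323) and the antiproliferative BTG1 (-0.44, 0.039) completed the set.

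The first 4 kept their calls in all 15 leave-one-out fits, and the last 5 depend on single libraries. CIART lost its call without TGFb + FT895 1 h replicate 2 (adjusted p 0.0579). The call ended in 4 of the 15 leave-one-out fits for EGLN1 (adjusted p up to 0.15, without TGFb + FT895 1 h replicate 2), in 5 for RAB20 (up to 0.126, without the same library), in 9 for PDGFB and in 12 for BTG1 (both up to 0.197, without TGFb + FT895 1 h replicate 1). The number of calls was 18 (8 up, 10 down) without TGFb 1 h replicate 2, 5 without TGFb 1 h replicate 3, 5 without TGFb + FT895 1 h replicate 1, 4 without TGFb + FT895 1 h replicate 2 and 19 (9 up, 10 down) without TGFb 12 h replicate 1. A fit with only the groups compared called 1 gene and none of these 9. PDGFB, KCTD11 and DDIT4 had been raised by TGFb alone and fell with FT895, and PPP1R3C fell in both comparisons. From independent draws 0.333 opposite and 0.475 equal directions were expected. The covariance between the TGFb and FT895 changes at 1 h was -0.0191. Simulated unchanged groups, which share the TGFb libraries in the same way, gave -0.0145 (SD 0.00071). The simulation draws genes independently, so its SD leaves out deviations that the genes of a library share. The gap therefore decides nothing about opposition by FT895.

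The hypoxia list followed its called genes: 20 of 25 members were lower with FT895 (2 called, PFKFB4 and EGLN1; 10 down adjusted over the list alone), with a median of -0.163 and an adjusted p of 1.76e-14 (0.00389 with an estimated correlation). It was the only list at 1 h whose call held with an estimated correlation. Further members included the vasodilator peptide ADM (-0.62, adjusted p 0.0744), the metastasis suppressor NDRG1 (-0.31, 0.112) and PFKFB3 (-0.34, 0.103), none of them called. The glycolysis list fell by a median of -0.169 (adjusted p 3.28e-14, and 0.0858 with an estimated correlation). It had 0 up and 1 down of 20, and 10 down adjusted over the list alone. With quantile normalization its median was -0.07 (adjusted p 0.00633). Mitochondrially encoded genes fell by a median of -0.238 with 0 of 13 called (9 down adjusted over the list alone; adjusted p 1.99e-13, 0.108 with an estimated correlation, 0.155 with quantile normalization; median -0.142 without TGFb 1 h replicate 2). The complex I gene MT-ND6 had -0.35 (adjusted p 0.0744).

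A further 3 lists were called down with 0 members called, in both counts, and none of them held with an estimated correlation. Cytosolic ribosomal proteins had a median of -0.134 (adjusted p 1.99e-13, and 0.666 with an estimated correlation), a median that turned to 0.035 (0.62) without TGFb 1 h replicate 1 and was -0.24 and -0.205 without replicates 2 and 3. Metallothioneins had -0.159 (0.0371, and 0.666 with an estimated correlation), which turned to 0.045 (0.918) without TGFb 1 h replicate 1, was -0.287 without replicate 2 and lost its call without TGFb + FT895 1 h replicate 3 (0.213). Cholesterol synthesis had -0.023 (0.0338, and 0.104 with an estimated correlation; 0.0818 and 0.0572 without TGFb 1 h replicates 2 and 3, 0.0958 without TGFb + FT895 1 h replicate 2; medians -0.037 and -0.04 without TGFb + FT895 1 h replicates 1 and 3). Collagens and extracellular matrix were not called (median 0.108, adjusted p 0.409), but without TGFb 1 h replicate 1 the median was -0.048 and the list was called down (0.00471), and without replicate 2 it was 0.195 and called up (0.000646). Matrix remodelling enzymes, not called with all libraries (0.262), were called down without replicate 1 (median -0.001, adjusted p 0.00471). SMAD targets had a median of 0.091 (adjusted p 0.708) with PDGFB as their called member. The remaining 19 lists had adjusted p of 0.194 or higher, and 6 of them held 2 or 3 called members adjusted over the list alone; DDIT4 was the called member of the ATF4 list over all genes. Immediate early genes were at 0.715 (EGR1 0.64, not called), NF-kB genes at 0.194 and NRF2 targets at 0.409. For the NF-kB, matrix enzyme, epithelial, tubular injury, mitosis, DNA replication, ATF4 and heat shock lists the median, mean and camera's direction did not share a sign.

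No landmark was called at 1 h with FT895. Log2 changes were 0 for SMAD7, 0.04 for SNAI1, 0.19 for SKIL, -0.02 for CCN2, 0 for COL1A1, 0.1 for COL4A1, 0.25 for FN1, 0.05 for VIM, 0.11 for CDH2, 0.17 for CPT1A and -0.06 for HDAC11, with adjusted p from 0.346 to 0.989.

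After 12 h, FT895 left the matrix and mesenchymal response to TGFb without a called landmark and raised HMOX1 and DDIT4. Genes of inflammatory signalling and of cholesterol synthesis shifted downward as groups. The comparison asks whether adding FT895 alters the state reached after 12 h of TGFb. Only 2 genes were called, both up, while 767 (6.15%) had an unadjusted p under 0.05.

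HMOX1, the heme oxygenase of the antioxidant response (chromosome 22, 35380361 to 35394214, plus strand), rose from 14.2 ± 0.963 to 24.4 ± 0.258 FPKM (log2 change 0.74, adjusted p 0.000391), on top of a rise of 0.81 with TGFb alone. DDIT4 rose from 102 ± 4.55 to 140 ± 9.31 FPKM (0.45, adjusted p 0.0115), the reverse of its fall at 1 h; it was the only gene called with FT895 at both times. Its call at 12 h was lost without TGFb 12 h replicate 1 (adjusted p 0.0968), TGFb 12 h replicate 3 or TGFb + FT895 12 h replicate 3. The number of called genes depends on TGFb 1 h replicate 1, which enters only through the shared spread: without it 44 genes were called (23 up, 21 down), including both of these. It was also 6 without TGFb 1 h replicate 2, 15 without TGFb 1 h replicate 3, 4 without TGFb + FT895 1 h replicate 3, 5 without TGFb 12 h replicate 2 and 1 without TGFb 12 h replicate 1, TGFb 12 h replicate 3 or TGFb + FT895 12 h replicate 3.

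Both genes had also risen with TGFb alone, so 0 genes were called in opposite directions and 2 in the same (0.489 and 0.283 expected). That 0 depends on the shared spread: without TGFb 1 h replicate 1, 27 of the 44 genes called with FT895 were called in opposite directions. Of the genes called with TGFb at 12 h, 63.2% had an FT895 change of opposite sign, but shared libraries by themselves produce opposition. The covariance was -0.0103, beyond the -0.00752 (SD 5e-04) of simulated unchanged groups. Genes were drawn independently there too, so the gap decides nothing about opposition by FT895. Landmarks had log2 changes of -0.16 for COL1A1 (40.5 ± 0.497 FPKM against 45.4 ± 0.452; adjusted p 0.88), -0.08 for SMAD7, 0.14 for SNAI1, -0.11 for SKIL, 0.03 for CCN2, -0.04 for COL4A1, 0.05 for FN1, 0.03 for VIM, 0 for CDH2, 0.18 for CPT1A (0.812) and 0.04 for HDAC11 (0.998), none of them called.

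Inflammatory cytokine and NF-kB genes moved down by a median of -0.195 with 0 of 26 called (9 down adjusted over the list alone; adjusted p 1.78e-13, and 0.00717 with an estimated correlation). The macrophage growth factor CSF1 (23.4 ± 0.64 to 16.8 ± 0.638 FPKM; -0.45, adjusted p 0.0516) and the NF-kB inhibitor NFKBIA (-0.25, 0.102) had the smallest p-values. Cholesterol synthesis genes moved down by a median of -0.089 with 0 of 29 called (2 down adjusted over the list alone; adjusted p 1.71e-06, and 0.00422 with an estimated correlation), with the isomerase IDI1 at -0.33 (0.23) and the sterol sensor INSIG1 at -0.2 (0.413). These 2 lists held their calls with an estimated correlation.

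ATF4 and unfolded protein response genes moved up by a median of 0.091 (1 called of 37, DDIT4, in both counts; adjusted p 1.21e-06, and 0.0595 with an estimated correlation; medians 0.139 and 0.055 without TGFb + FT895 12 h replicates 1 and 3). NRF2 targets had a median of 0.062 (1 called of 24, HMOX1, in both counts; adjusted p 0.0136, and 0.0908 with an estimated correlation), and lost the call without TGFb 12 h replicate 1 (0.279, median 0.029) or TGFb + FT895 12 h replicate 3 (0.122, median 0.041). Heat shock genes had 0.077 with 0 of 23 called in both counts (0.00546, and 0.452 with an estimated correlation; 0.122 and median 0.038 without TGFb + FT895 12 h replicate 3); the chaperone HSPH1 was at 0.16 (0.608). Matrix remodelling enzymes had -0.045 with 0 of 27 called in both counts (0.0136, and 0.589 with an estimated correlation; 0.223 without TGFb 12 h replicate 2, and 0.141 with a median of -0.025 without TGFb + FT895 12 h replicate 2), among them the collagen hydroxylase PLOD2 at -0.2 (0.419). Epithelial junction genes had -0.048 with 0 of 21 called in both counts (0.0439, and 0.452 with an estimated correlation). That call was lost in 6 leave-one-out fits: 0.0513, 0.0537 and 0.051 without mock replicate 1, mock replicate 2 and TGFb + FT895 1 h replicate 1, and 0.154, 0.178 and 0.195 without TGFb 12 h replicates 2 and 3 and TGFb + FT895 12 h replicate 2. Its median was -0.019 without TGFb 12 h replicate 2 and -0.086 without TGFb + FT895 12 h replicate 3.

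Hypoxia genes at 12 h had a median of 0.08, with 15 of 25 members higher and 0 called (7 up and 4 down adjusted over the list alone; adjusted p 0.157; 0.0337 without TGFb + FT895 12 h replicate 1). Glycolysis genes had a median of -0.053 against a mean of 0.024 (0 called, 5 up adjusted over the list alone; 0.897), with the glucose transporter SLC2A3 at 0.43 (0.0516) and HK2 at 0.48 (0.0552). Mitochondrially encoded and ribosomal genes were not called (0.677 and 0.217), nor were SMAD targets (0.896; HMOX1 up, 2 up adjusted over the list alone), collagens (0.217), mesenchymal genes (0.983) or proximal tubule genes (0.572). The other 13 lists had adjusted p from 0.126 (mitosis) to 0.914 (Kruppel-like factors and metallothioneins). Ribosomal proteins were called down without TGFb 12 h replicate 1 (-0.057, 0.00135) or TGFb + FT895 12 h replicate 3 (-0.045, 0.0224), mitosis down without TGFb 12 h replicate 3 (0.0149) and immediate early genes up without TGFb + FT895 12 h replicate 2 (0.0259). For the SMAD target, mesenchymal, deacetylase, Kruppel-like, DNA replication, p53 and metallothionein lists the median, mean and camera's direction did not share a sign.

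The effect of FT895 on low-oxygen genes differed between 1 h and 12 h, which the interaction tested directly. The hypoxia list was called down at 1 h and was not called at 12 h. It called 21 genes, 18 of them with a more positive effect at 12 h. DDIT4 (interaction 1.1, adjusted p 2.67e-05), PFKFB4 (1, 4.85e-05) and PPP1R3C (1.21, 4.85e-05) led. ADM (1.22, 0.00642) went from 7.36 ± 1.38 to 4.42 ± 0.441 FPKM with FT895 at 1 h and from 4.99 ± 0.561 to 8.15 ± 1.06 at 12 h. HILPDA, a lipid-droplet gene induced by hypoxia, had 1.07 (0.0137; up to 0.055 without TGFb + FT895 1 h replicate 2, and the call was lost in 4 of the 15 leave-one-out fits). In the other direction, the transferrin receptor TFRC, the main door for iron, had -0.75 (0.00704): 0.31 at 1 h and -0.44 at 12 h. The cytochrome CYP1B1 (-0.63, 0.0356) and SHISA2 (-0.61, 0.0465), an endoplasmic reticulum gene that holds back WNT and FGF receptors, lost their calls in 13 and 12 of the 15 leave-one-out fits (adjusted p up to 0.118 without TGFb + FT895 12 h replicate 2 and 0.173 without TGFb + FT895 1 h replicate 2).

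The number of interaction genes was 8 without TGFb + FT895 1 h replicate 2, 13 without TGFb 12 h replicate 1, 13 without TGFb 12 h replicate 2 and 10 without TGFb + FT895 12 h replicate 3; without TGFb 1 h replicate 1 it was 28, which included all 21. The hypoxia list had an interaction median of 0.19 (5 up, 0 down of 25; 11 up adjusted over the list alone; adjusted p 3.84e-11, and 0.0108 with an estimated correlation). Of its 25 members 20 were lower at 1 h, 15 were higher at 12 h and 13 were both. Those margins alone give a count near 13, so it does not show a reversal member by member. Across all genes the FT895 changes at the 2 times had a Pearson r of 0.063 and a Spearman correlation of 0.071, with a range of r from -0.011 without TGFb 12 h replicate 2 to 0.162 without TGFb 12 h replicate 1; genes are not independent replicates.

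**Figure D4:**
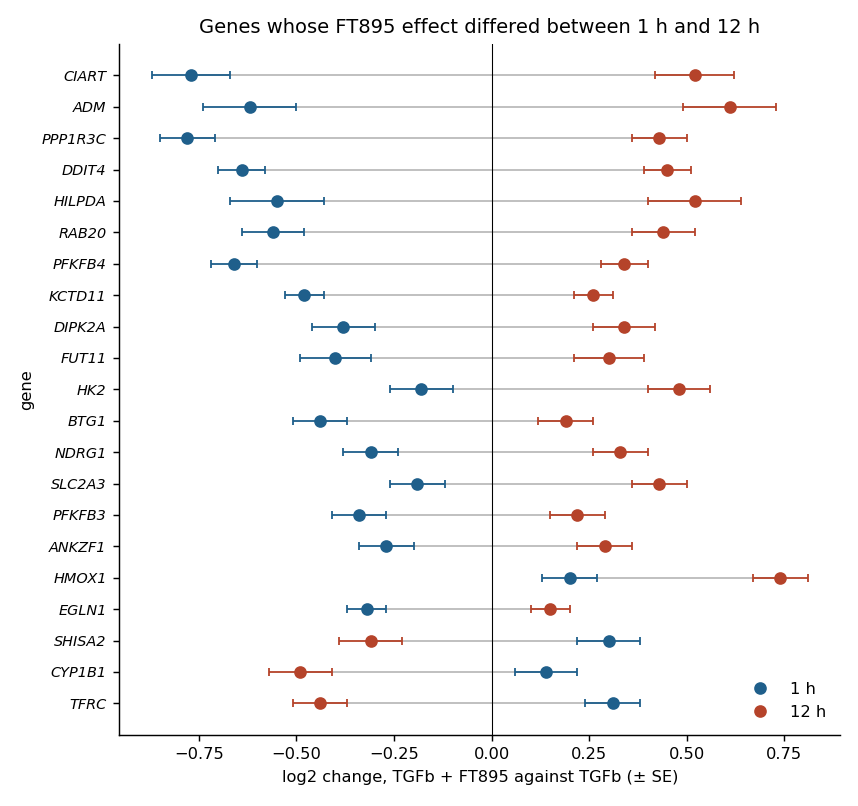
Log2 change with FT895 at 1 h and at 12 h (± SE, n = 3 per group) for the 21 genes of the interaction, 1 line per gene with a point for each time. DDIT4 lies at -0.64 at 1 h and 0.45 at 12 h.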

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

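Of the technical explanations weighed here, removal of a transcript length trend as the whole cause of the library that stands apart was chosen only after that library's length trend was seen; the others were fixed earlier. No biological explanation was tested.

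The effect of FT895 on low-oxygen genes differed between the 2 times. The hypoxia list was called down at 1 h (median -0.163) and was not called at 12 h (0.08, adjusted p 0.157). Of its 25 members 20 were lower at 1 h, 15 were higher at 12 h and 13 were both, a count near what those margins alone give. TGFb at 12 h against 1 h called 5113 genes, but that comparison also holds time in culture, since no mock matches either time. The interaction called 21 genes. Those more positive at 12 h were CIART (1.29), ADM (1.22), PPP1R3C (1.21), DDIT4 (1.1), HILPDA (1.07), PFKFB4 (1), RAB20 (1), KCTD11 (0.74), DIPK2A (0.72), FUT11 (0.7), HK2 (0.66), NDRG1 (0.63), BTG1 (0.63), SLC2A3 (0.62), ANKZF1 (0.56), PFKFB3 (0.56), HMOX1 (0.54) and EGLN1 (0.47). Of these 18, the hypoxia list holds 5: ADM, EGLN1, NDRG1, PFKFB3 and PFKFB4. SHISA2 (-0.61), CYP1B1 (-0.63) and TFRC (-0.75) went the other way.

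TGFb 1 h replicate 1 does not carry the fall at 1 h: without it the hypoxia median at 1 h was -0.17 (adjusted p 1.7e-15). A gene length or GC trend does not account for the values either: after removing a cubic trend on both the median was -0.182 at 1 h and 0.066 at 12 h, over 11536 genes (92.5%) and all 25 members. Of 100 splits of the 12 libraries within each time, 3 called as many genes as the real grouping of 21, the real one included, and the highest other split called 207. A split calling many times the real count points to a structure of the samples: the splits with 207 and 90 calls both put TGFb 12 h replicate 1 with TGFb + FT895 12 h replicates 1 and 2, and the one with 207 also parts TGFb 1 h replicate 1 from replicates 2 and 3. The one with 90 keeps the real grouping at 1 h with its labels exchanged, so it still holds the real FT895 contrast at 1 h. Such a structure is not excluded as a source of the pattern, and no batch is recorded.

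Among lists, the interaction was called for hypoxia (0.19), glycolysis (0.076, adjusted p 2.73e-08, and 0.243 with an estimated correlation), NF-kB genes (-0.181; 0.00094, then 0.25), ATF4 genes (0.052; 0.00379, then 0.267), NRF2 targets (0.076; 0.00424, then 0.117), heat shock (0.061; 0.0097, then 0.536), mitochondrially encoded genes (0.239; 2.73e-08, then 0.259) and cytosolic ribosomal proteins (0.112; 3.36e-06, then 0.626). Hypoxia alone held with an estimated correlation (0.0108). The ribosomal value was -0.067 (0.0799) without TGFb 1 h replicate 1, and 0.221 and 0.186 without replicates 2 and 3. The mitochondrial value was 0.139 without TGFb 1 h replicate 2, and the glycolysis value was 0.024 and 0.116 without TGFb 12 h replicates 1 and 2. ATF4 genes lost the call without TGFb + FT895 12 h replicate 3 (0.026, 0.0753) and were at 0.022 without TGFb + FT895 1 h replicate 2. Heat shock genes lost it without TGFb 1 h replicate 1 (0.009, 0.11), TGFb 12 h replicate 3 (0.0599) and TGFb + FT895 12 h replicate 3 (0.0753), and were at 0.132 and 0.101 without TGFb 1 h replicate 2 and TGFb 12 h replicate 1. NRF2 targets were at 0.046 and 0.049 without TGFb + FT895 1 h replicates 1 and 2, and at 0.05 without TGFb 12 h replicate 1. Not called with all libraries, collagens reached 0.000167 and 0.0366, and metallothioneins 0.0122 and 0.0366, without TGFb 1 h replicates 2 and 3.

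TGFb 1 h replicate 1 stands apart from its group along transcript length. The Spearman correlation across genes of its deviation with transcript length was -0.486, against -0.222 to 0.162 in the 12 libraries of other groups and 0.431 and 0.36 in its partners, so longer transcripts were lower in it, which is consistent with RNA degradation or a shorter fragment size. GC content gave -0.242, and other libraries reached -0.408 and 0.359, so a GC trend cannot be told apart from what other libraries show. Neither trend is the whole cause: the SD of the deviation was 0.315, and 0.307 after removing GC, 0.275 after removing length and 0.246 after both, still above the highest of the other groups at 0.188. Its 50 highest loci held 25% of the signal, inside the 23.3 to 27.4% of all libraries, which argues against a few genes taking the signal. A mislabelled mock library is argued against by its response to TGFb, which was 0.9 of that of its partners over 69 genes.

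More genes were lower than higher after 12 h of TGFb, with 36.7% higher. With median-of-ratios scaling 52.9% were higher, but that scaling centres the ratios of each library, which draws the share toward 50%. The shift in share therefore decides nothing, and the imbalance stays open between scaling and expression.

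For single comparisons, the 10 splits of 6 libraries are too few for a share under 0.05. The real grouping was in each case the 1 split with the most calls: 1119 against 2 for TGFb at 1 h, 4814 against 1 for TGFb at 12 h, 9 against 3 for FT895 at 1 h, 2 against 0 for FT895 at 12 h and 5113 against 0 between the TGFb times. Other splits mix the groups, which adds any real difference between them to the shared spread and lowers their calls. The gap to those splits is therefore no measure of chance.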

How the results depend on the processing

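Counts of called genes moved with a threshold on the log2 change, with the weighting of libraries, with a fit of only the groups compared and with single libraries, and the cause was not tested. TGFb at 1 h called 736 genes with no filter on low values, 3985 with library weights, 373 with only the groups compared, 61 at an absolute log2 change of at least 1, and 416 (without mock replicate 3) to 1520 (without TGFb 1 h replicate 2) over the leave-one-out fits. TGFb at 12 h called 389 at an absolute log2 change of at least 1 and 3877 to 5844 with 1 library left out. TGFb at 12 h against 1 h called 3188 with only the groups compared, 300 at an absolute log2 change of at least 1 and 4369 to 5310 with 1 library left out. FT895 at 1 h called 16 genes with median-of-ratios scaling, 1974 with library weights (1434 up, 540 down), 1 with only the groups compared and 4 to 19 with 1 library left out. At an absolute log2 change of at least 1 limma called 0, with 1720 genes at an unadjusted p under 0.05. FT895 at 12 h called 6 with a pseudocount of 0.1, 5 with no filter, 14 at FPKM of at least 5 in 3 libraries, 7 with median-of-ratios scaling, 5 with quantile normalization, 59 with library weights, 1 with a replicate block, 1 with only the groups compared and 1 to 44 with 1 library left out. At an absolute log2 change of at least 1 limma called 0 there, with 767 genes at an unadjusted p under 0.05. The interaction called 59 with library weights, 11 with only the groups compared, 6 at an absolute log2 change of at least 1 and 8 to 28 with 1 library left out.

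Library weights gave TGFb 1 h replicates 1, 2 and 3 weights of 0.11, 0.64 and 5.11, against 0.44 to 1.75 in the other groups. With weights the TGFb 1 h group therefore rests largely on replicate 3. Treating equal replicate numbers as a block called 867, 4756, 8, 1, 4973 and 15 genes in the order TGFb at 1 h, TGFb at 12 h, FT895 at 1 h, FT895 at 12 h, TGFb at 12 h against 1 h, and the interaction. The numbers do not pair samples here: the correlation of residuals between equal numbers ran from -0.061 to 0.088 over 15 pairs of libraries. Genes called in opposite directions by FT895 and TGFb numbered 3 at 1 h, and 8 with median-of-ratios scaling, 1239 with library weights, 0 with only the groups compared, 0 at an absolute log2 change of at least 1 and 2 to 10 with 1 library left out. At 12 h they numbered 0 in the limma fit of all libraries, and 1 with a pseudocount of 0.1, 2 with no filter, 6 at FPKM of at least 5, 1 with median-of-ratios scaling, 37 with library weights and 0 to 27 with 1 library left out. The 27 came from the fit without TGFb 1 h replicate 1. The Pearson r of the FT895 effects at the 2 times ran from -0.011 to 0.162.

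Gene lists depended on the assumed correlation within a list. The number called was 7, 10, 6, 7, 10 and 8 in the same order, 3, 3, 1, 2, 2 and 1 with an estimated correlation, and 11, 19, 3, 4, 23 and 4 with fry. Quantile normalization left 2 for FT895 at 1 h and 4 for the interaction. With 1 library left out the ranges were 6 to 10, 10 to 11, 5 to 6, 5 to 8, 10 to 11 and 6 to 10. Among the lists called with all libraries, a direction reversed in 5 cases: glycolysis with TGFb at 1 h (-0.045, adjusted p 0.591, with quantile normalization), metallothioneins and cytosolic ribosomal proteins with FT895 at 1 h (0.045, 0.918, and 0.035, 0.62, without TGFb 1 h replicate 1), and the ribosomal interaction (-0.015, 0.876, with library weights; -0.067, 0.0799, without TGFb 1 h replicate 1). With 1 library left out, the metallothionein median ran from -0.287 to 0.045, the ribosomal one with FT895 at 1 h from -0.24 to 0.035 and the ribosomal interaction from -0.067 to 0.221. Of the single-gene results over all settings, 8252 stayed the same, 448 were weaker, 94 stronger, 64 moved and 0 reversed. Read depth is unknown, so counting noise cannot be modelled and low genes carry a spread that FPKM does not show.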

Other observations

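The genes below were chosen after their values were seen. Genes of the chorionic gonadotropin beta cluster on chromosome 19 (49015980 to 49058860) had higher values after 12 h of TGFb. CGB5 (log2 change 4.38), CGB8 (4.14) and CGB3 (3.07) were joined by CGB7, which went from 0.323 to 8.49 FPKM (2.84), CGB1 (2.40), CGB2 (1.85) and LHB (1.77), the luteinizing hormone subunit from which the family arose. At 1 h CGB7 was already higher (0.93, adjusted p 3.87e-06), as were CGB5 (0.67, 0.0148) and CGB8 (0.60, 0.00354). FT895 called none of them. The copies are near identical, so which of them carries the reads is uncertain, and reads of 1 or 2 copies spread over the others are not excluded.

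Of the ligands of the EGF receptor, AREG, EREG, TGFA and BTC fell at 12 h. AREG (-3.55) and EREG (-2.67) lie close together on chromosome 4, and TGFA on chromosome 2 fell from 12.3 to 7.92 FPKM (-0.57, adjusted p 1.29e-05) and BTC from 1.31 to 0.327 (-0.80, 0.000133). HBEGF, the heparin-binding member, was at 0.08 (0.199) and the receptor EGFR at 0.22 (0.235), neither called.

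The inhibitors of differentiation marked the early wave. ID1, ID2 and ID3 rose by 2.41, 1.65 and 1.67 at 1 h, and between 1 h and 12 h they fell by 2.33, 2.26 and 1.18. At 12 h ID1 was at 0.08 (adjusted p 0.594), ID2 had fallen below mock (-0.61) and ID3 was above it (0.49). MYC fell from 102 to 60.1 FPKM at 1 h (-0.76) and was at 0.05 at 12 h (0.586). COL4A2 and COL7A1 rose by 0.47 and 0.60 at 12 h, while the laminin chain LAMA3 fell by 0.75. The cytokine gene IL6 fell by 0.76 at 12 h while IL11 rose, although both signal through the same gp130 chain.

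When TGFb 1 h replicate 1 was left out, FT895 at 12 h called 44 genes. NPPB, the natriuretic peptide, was at -0.7, DLX2 at -0.52, CSF1 at -0.45, TFRC at -0.44, the death ligand TNFSF10 at -0.43, IGFBP3 at -0.29 and NFKBIA at -0.25, while HK2 was at 0.48, the polyamine enzyme ODC1 at 0.39, the lipid-droplet coat PLIN2 at 0.36 and TXNIP at 0.25. At 1 h the same omission added SLC2A1 (-0.31), NDRG1 (-0.37), PFKFB3 (-0.43), MT-ND5 (-0.39) and REPS1 (-0.41) to the genes that fell, and HOXA9 (0.35) rose.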
